A study of Arabidopsis thaliana with 3 samples.

How the data were processed

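The material was Arabidopsis leaf tissue, 4 g per immunoprecipitation, with nuclei digested with micrococcal nuclease for 15 min and libraries read as 50 bp pairs, per the labels' protocols. The labels give 3 libraries, 1 control, 1 H2A.W.6 immunoprecipitation and 1 H2A.W.7 immunoprecipitation. The control was not analysed here on its own. The authors deposited 4 lists of regions, 1 for the arms and 1 for the centromeric part of each immunoprecipitation, with a chromosome, a start and an end per region and no height, score or p-value. The submitters' processing notes name TAIR10 as the genome build and bedtools as a tool, and the aligner, the caller, the threshold and the scaling against the control are not given in the sources used here. The lists themselves show starts and ends on a grid of 5 bp, apart from 2 ends of the H2A.W.7 arm list, a smallest region of 200 bp and no overlaps, with gaps of 5 bp after 16.0% of the centromeric H2A.W.6 regions and 8.64% of the H2A.W.7 ones. The number of regions therefore depends on small breaks, and covered length was preferred to it. The depth per library is unknown, and because a longer list can come from deeper reading or a looser threshold, neither can be told from the lists.

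The border between arms and centromeric part was taken as the only multiple of 100 kb between the last arm region and the first centromeric region on each side. This gave 12.4 to 17.5 Mb on chromosome 1, 1.4 to 7.3 Mb on chromosome 2, 11.4 to 15.9 Mb on chromosome 3, 1.4 to 6.1 Mb on chromosome 4 and 9.8 to 14.7 Mb on chromosome 5. Genes came from a RefSeq gene table of the TAIR10.1 assembly with 38312 genes, of which 37899 were nuclear with coordinates. Because its name differs from that of the lists' build, the table was checked by moving it along the chromosomes by up to 10000 bp either way, and the cover of arm pseudogenes by H2A.W.6 was highest with no shift on 5 of 5 chromosomes. No gene coordinate is printed, and region positions are those of the lists, counted from 1. The table holds no exons, introns, strand or transposon annotation, so the exon and intron shares planned beforehand were not analysed here. Transposon genes stand in its pseudogene class, as did 8 of the 10 silenced loci of the fixed list. With no genome sequence, GC content and the share of unique 50-base windows were not analysed here either.

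Regions of the 2 immunoprecipitations were compared by overlap of 1 bp or more in each direction and by the Jaccard index. Random placement set the regions of a list down without overlap, in random order and with random gaps, inside the same arm or centromeric part, 1000 times. The plan named bedtools for overlap and shuffling, and the calculations were made in Python instead. A trial of non-overlapping bedtools shuffles left some centromeric regions unplaced, so shuffles were compared in the arms alone. Overlap counts by bedtools were the same, at 3501 and 3220 arm regions and 11117 and 15884 centromeric regions. In 20 bedtools shuffles, which may move a region between the arms of a chromosome, the median arm Jaccard index was 0.0161, against 0.0190 by placement inside each arm. Placements describe what position alone would give and are not replicate tests. Intervals of shares are 95% Wilson intervals over regions or genes.

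A gene was counted as covered when at least 50% of its body lay in the regions of an immunoprecipitation. The gene lists, the comparisons of the design, most of the alternatives and the rule for naming were fixed before the data were examined, and the other alternatives and the closing tests came later. The 7 lists hold 72 genes, all matched, for H2A variants, DNA damage response, silencing machinery, known silenced loci, Polycomb targets, leaf and housekeeping genes and NLR resistance genes. Each was set beside 10000 random lists of protein-coding genes matched on compartment and length class. Named were list members covered by either variant, the 10 genes of 1 kb or more with the largest difference each way, and the 3 longest regions, and the 3 longest with no base in the other list, per variant and compartment. Other members of the lists and other genes were named after their values were seen, and the value of 1 list member is not reported here.

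The calculations were tested on simulated lists. Lists of the same lengths placed independently gave a mean Jaccard ratio of 1.00 in both compartments over 20 simulations, with the value inside the central 95% of placements in 19 arm and 18 centromeric simulations. Where regions on pseudogenes were kept 5 times as often, the pseudogene ratio found was 4.16 against a true 4.11 in the arms and 1.92 against 1.92 in the centromeric part. Of 200 genes covered over 55% or 45% of the body, the 100 above the limit were counted in each compartment. Alternatives were a stricter list (regions at or above the median length), each chromosome left out, other overlap rules, circular shifts, merging within 1000 bp, thinning of the longer list in 100 draws, other gene limits and other bin sizes. They used 200 placements, or 2 per thinning draw. A further 4 alternatives, counted as 6 because 2 of them serve 2 results each, were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.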

Results

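Chromatin of Arabidopsis thaliana leaves aged 2 to 3 weeks was digested with micrococcal nuclease, which cuts between nucleosomes, and immunoprecipitated for H2A.W.6 or H2A.W.7. Both are histones of the H2A.W class, which is known to mark plant heterochromatin, and H2A.W.7 is known to carry a C-terminal motif of the kind that the damage kinase ATM phosphorylates. The series concerns how the response to DNA damage is divided between heterochromatin and euchromatin, and the comparison its design allows is where along the genome the 2 variants lie. Each immunoprecipitation was 1 library, and 1 control library served as the reference for both. The lists held 18107 enriched regions for H2A.W.6 and 25393 for H2A.W.7, each split by the submitters into chromosome arms and a centromeric part. They held positions only, with no heights or read counts, so the depth is unknown, no difference between the variants has a replicate check, and no p-value is given. Ranges over the 5 chromosomes describe how even a value was along the genome and are not replicates.

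H2A.W.6 and H2A.W.7 were both concentrated in the centromeric part, H2A.W.6 more so. H2A.W.6 regions covered 14.6 Mb or 58.1% of the centromeric span, and H2A.W.7 regions covered 11.4 Mb or 45.2%. In the arms the order was the opposite, with 2.25 Mb or 2.39% for H2A.W.6 and 4.42 Mb or 4.70% for H2A.W.7. The covered length with H2A.W.7 was therefore 1.96 times that with H2A.W.6 in the arms (1.85 to 2.04 across the 5 chromosomes) and 0.778 times in the centromeric part (0.751 to 0.820). Both ratios were lower among long regions, a split chosen after seeing the data, at 1.86 and 0.476 for regions of 1000 bp or more and 1.42 and 0.322 for those of 2000 bp or more. The centromeric part makes up 21.1% of the sequence and held 86.6% of the covered bases of H2A.W.6 and 72.0% of those of H2A.W.7. Covered share was 24.3 times as high in the centromeric part as in the arms for H2A.W.6 and 9.63 times as high for H2A.W.7.

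Arm regions numbered 3982 for H2A.W.6 and 7750 for H2A.W.7, with median lengths of 360 and 395 bp. Centromeric regions numbered 14125 and 17643, with median lengths of 575 bp for H2A.W.6 and 430 bp for H2A.W.7, so H2A.W.7 had more but shorter regions there. Along the arms, H2A.W.7 covered more than H2A.W.6 in 859 of 937 bins of 100 kb. It covered less in 185 of 251 centromeric bins. The covered shares of the 2 variants rose and fell together across bins, with Pearson's r of 0.930 and Spearman's rho of 0.864 in the arms, and 0.864 and 0.879 in the centromeric part. These are correlations across genomic bins, which are not independent replicates. In the 66 centromeric bins where H2A.W.6 covered 80% or more, the median share was 88.3% for H2A.W.6 and 61.6% for H2A.W.7. In the 28 centromeric bins where H2A.W.6 covered under 20%, the medians were 14.7% and 20.3%. Both sets of bins were picked by the H2A.W.6 share itself, so part of either gap may come from that choice.

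**Figure D1:**
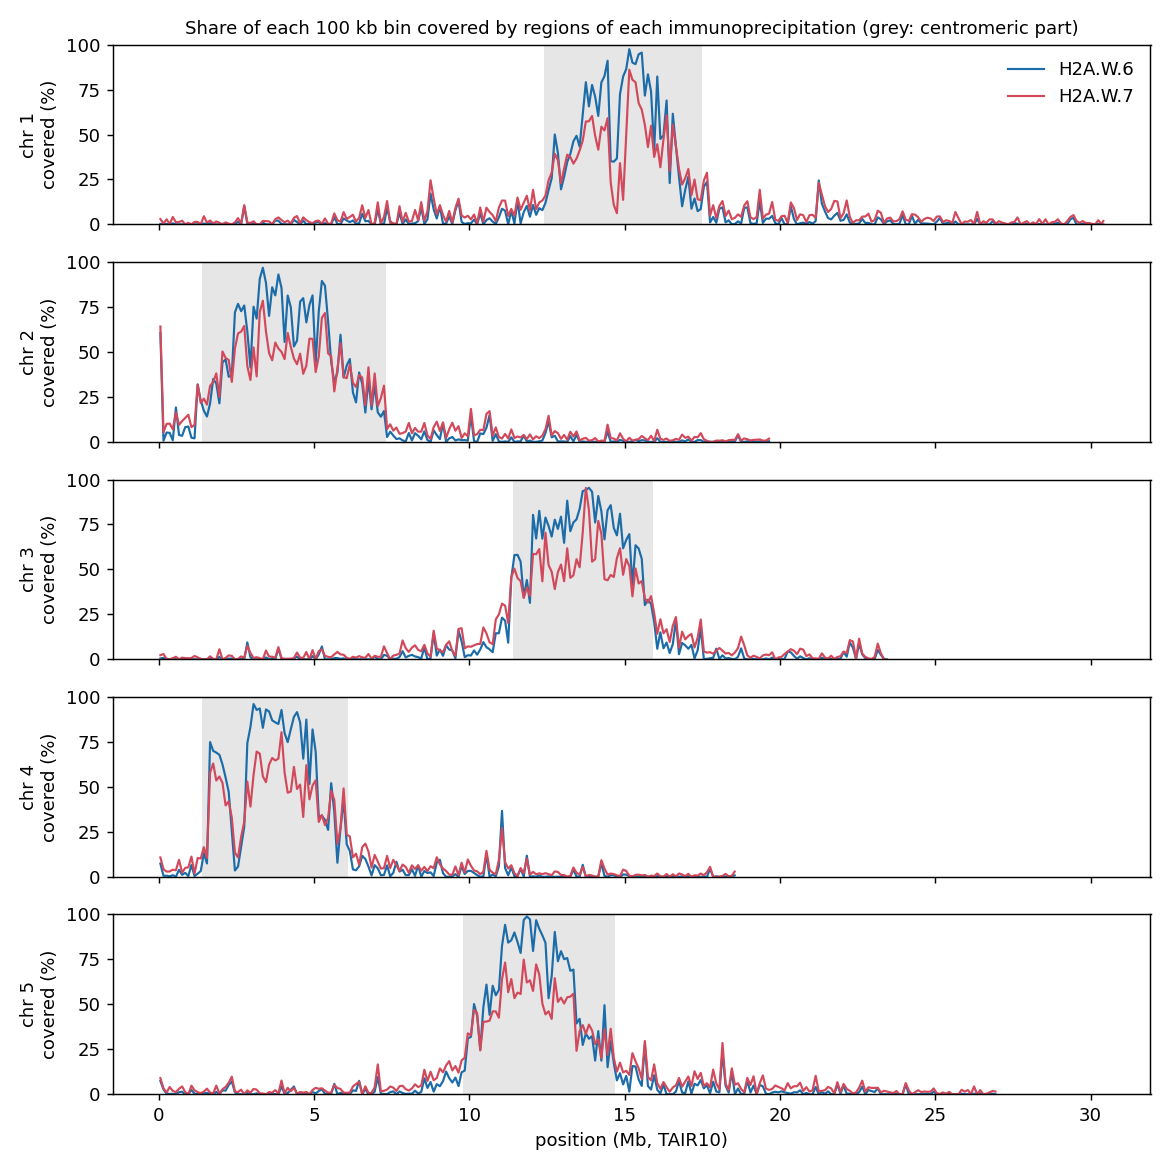
Share of each 100 kb bin covered by regions (y axis, percent) along the 5 chromosomes (x axis, Mb), with H2A.W.6 in blue, H2A.W.7 in red and the centromeric part shaded grey. H2A.W.6 lies above H2A.W.7 over most of the shaded parts, in 185 of 251 bins, and H2A.W.7 lies above H2A.W.6 over most of the arms, in 859 of 937 bins.

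In the arms, most H2A.W.6 regions met an H2A.W.7 region at an overlap of 1 bp, while most H2A.W.7 regions met no H2A.W.6 region. At an overlap of 1 bp or more, 87.9% of the H2A.W.6 arm regions met an H2A.W.7 region (3501 of 3982, 95% Wilson interval 86.9 to 88.9), and 41.5% of the H2A.W.7 arm regions met an H2A.W.6 region (3220 of 7750, 40.5 to 42.6). The share of H2A.W.6 fell to 48.4% with the H2A.W.7 list thinned to its length and to 39.4% when 50% of both regions had to overlap, where that of H2A.W.7 was 20.2%. Bases found with H2A.W.7 alone came to 2.58 Mb of the arms, against 0.412 Mb found with H2A.W.6 alone. In the centromeric part the asymmetry was the other way, with 4.75 Mb covered by H2A.W.6 alone and 1.51 Mb by H2A.W.7 alone. There 78.7% of the H2A.W.6 regions (11117 of 14125, 78.0 to 79.4) and 15884 of the 17643 H2A.W.7 regions (89.6% to 90.5%) met a region of the other variant. That order turned with 50% of both regions, 34.9% and 28.0%, after merging within 1000 bp, 94.5% and 84.8%, and with the H2A.W.6 list thinned, 78.7% and 72.6%. Thinning drops whole regions at random, so it lowers the share of the other list by construction, here and in the arms. The intervals cover counting error only and treat neighbouring regions as independent, which they are not.

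Random placement of the H2A.W.7 regions inside the same arms gave a Jaccard index, the shared bases over the bases covered by either list, of 0.0190 (central 95% of 1000 placements, 0.0162 to 0.0218), and the observed index was 0.381. In the centromeric part the observed index was 0.611 and the random one 0.345 (0.341 to 0.348), a ratio of 1.77. With so much of the centromeric part covered, the share of H2A.W.6 regions that met an H2A.W.7 region by chance was already 76.3%. When placement was kept inside windows of 500 kb, an alternative chosen after seeing the data, the observed arm index was 10.6 times the random one. Both lists were made against 1 control library, so part of the overlap may come from that library, and it cannot be split.

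The longest regions lay mostly over rRNA genes, pseudogenes and a copy of organelle DNA. At the left end of chromosome 2, positions 1001 to 10365 for H2A.W.6 and 991 to 10425 for H2A.W.7 were covered over the rRNA genes AT2G01010 and AT2G01020, next to the nucleolus organiser. H2A.W.6 also covered chromosome 2, 15701 to 26630, with the pseudogenes AT2G01024, AT2G01026 and AT2G01028, and 42056 to 49995, at the pseudogene AT2G01034. The other long H2A.W.7 arm regions were chromosome 2, 10592016 to 10604705, with 6 pseudogenes from AT2G24890 to AT2G24930, and chromosome 1, 7065991 to 7075870, with the pseudogene AT1G20390 and the protein-coding gene AT1G20400. The longest centromeric H2A.W.6 region spanned 56.58 kb of chromosome 2, 3245646 to 3302225, and met 42 genes, 26 of them protein-coding. This stretch belongs to a copy of mitochondrial DNA that chromosome 2 is known to carry. The next were chromosome 4, 3974431 to 4007580, with 4 pseudogenes from AT4G06710 to AT4G06716, and chromosome 4, 2922631 to 2950015, with no annotated gene, where 32.0% of the bases were shared with H2A.W.7. The longest centromeric H2A.W.7 regions were chromosome 4, 3965536 to 3987265 (pseudogene AT4G06708), chromosome 4, 3676911 to 3692045 (4 pseudogenes from AT4G06602 to AT4G06605), and chromosome 2, 6716751 to 6729385 (pseudogene AT2G15410 and protein-coding AT2G15420). Unique sequence was not analysed, so at the rRNA genes and the mitochondrial copy, reads from other copies cannot be told apart.

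Regions with no base in the other list were short. The longest such H2A.W.7 arm region, chromosome 4, 6699181 to 6701280, met the transcriptional coactivator gene KELP. The next were chromosome 3, 10262176 to 10264040, outside annotated genes, and chromosome 2, 7680836 to 7682540, at SDC, an F-box gene known to be silenced by DNA methylation. For H2A.W.6 the longest such arm regions were chromosome 3, 10108501 to 10109895 (pseudogene AT3G27327), 16692826 to 16694200 (pseudogene AT3G45520) and 20201931 to 20203300 (protein-coding AT3G54580). The centromeric ones of H2A.W.7 were chromosome 2, 2330231 to 2332360 (AT2G06002 and FIP1), chromosome 4, 5743071 to 5744995 (pseudogenes AT4G08953 and AT4G08956) and chromosome 2, 7240596 to 7242490 (no gene). Those of H2A.W.6 were chromosome 1, 14472376 to 14474715 (no gene), chromosome 4, 3585341 to 3587535 (pseudogene AT4G06585) and chromosome 2, 5255761 to 5257875 (pseudogene AT2G12800).

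Pseudogenes, the annotation class that holds most transposon-derived genes, took the largest share of the arm bases of H2A.W.6, and sequence between genes took most of those of H2A.W.7. For H2A.W.6 the pseudogene share was 47.4%, 21.1 times the share of random placements, and for H2A.W.7 it was 22.5%, 10.7 times. Protein-coding gene bodies took 17.4% and 14.9%, which was 0.276 and 0.235 times random placement. Sequence outside annotated genes took 33.0% of the arm bases of H2A.W.6 (1.01 times random) and 59.7% of those of H2A.W.7 (1.84 times). The gene table holds no transposon annotation, so transposons not listed as genes would count as outside annotated genes. With placement kept inside 500 kb windows, an alternative chosen after seeing the data, the pseudogene ratios were 10.5 for H2A.W.6 and 6.10 for H2A.W.7.

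The 4530 arm regions found with H2A.W.7 alone differed from the shared ones in where they lay. Of their bases 81.4% were outside annotated genes (2.52 times random) and 2.91% in pseudogenes (1.45 times), whereas the 481 arm regions found with H2A.W.6 alone had 43.8% of their bases in pseudogenes (19.6 times). With transposons not annotated as such, these shares cannot show whether regions of H2A.W.7 alone avoid them. In the centromeric part, pseudogenes took 46.5% of the H2A.W.6 bases (1.51 times random) and 40.7% of the H2A.W.7 bases (1.32 times), and protein-coding genes took 4.97% and 5.34% (0.308 and 0.329 times). The 1759 centromeric regions found with H2A.W.7 alone had 85.6% of their bases outside annotated genes and 4.84% in pseudogenes, 0.161 times random placement. These regions were picked for holding no H2A.W.6 base, while placements could fall anywhere in the part. H2A.W.6 covered on average 87.8% of a centromeric pseudogene and 58.1% of the span, so these shares follow in part from that choice. The same limit holds for the arm regions found with a single variant.

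At a limit of 50% of the gene body, H2A.W.7 covered fewer pseudogenes of the centromeric part than H2A.W.6. Counting a gene as covered when 50% or more of its body lay in regions, 2935 of 3155 centromeric pseudogenes were covered by H2A.W.6 (93.0%, 95% Wilson interval 92.1 to 93.9) and 2078 by H2A.W.7 (65.9%, 64.2 to 67.5), with H2A.W.7 lower on 5 of 5 chromosomes. The gap depended on the limit, since 3030 and 2971 had any base covered, and after merging regions within 1000 bp 2982 and 2563 were covered. The H2A.W.6 list thinned to the length of the H2A.W.7 list covered 2266, against 2078. Thinning drops whole regions at random and so lowers such counts by construction. It cannot show what a shallower or stricter list would cover. Of the 762 arm pseudogenes, 434 were covered by H2A.W.6 and 445 by H2A.W.7, 366 of them by both. Covered protein-coding genes of the arms numbered 267 of 25344 for H2A.W.6 and 461 for H2A.W.7, with 231 in both. In the centromeric part 621 and 510 of 2100 protein-coding genes were covered. Without chromosome 2, which held 648 of these genes, the counts were 401 and 333. That order turned with any base covered, 766 and 836, and with the H2A.W.6 list thinned, 473.5 and 510. Between 3.2 and 3.7 Mb of chromosome 2, an interval at the mitochondrial copy chosen after seeing the data, 98 of 104 protein-coding genes were covered by H2A.W.6 and 79 by H2A.W.7. Unique sequence was not analysed, so this cover cannot be assigned to the nuclear copy alone. At a limit of 90% of the body, the centromeric pseudogenes covered were 2260 for H2A.W.6 and 859 for H2A.W.7, and when the H2A.W.7 arm list was thinned to the length of the H2A.W.6 list, it covered 214 arm protein-coding genes and a median of 182.5 arm pseudogenes.

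**Figure D2:**
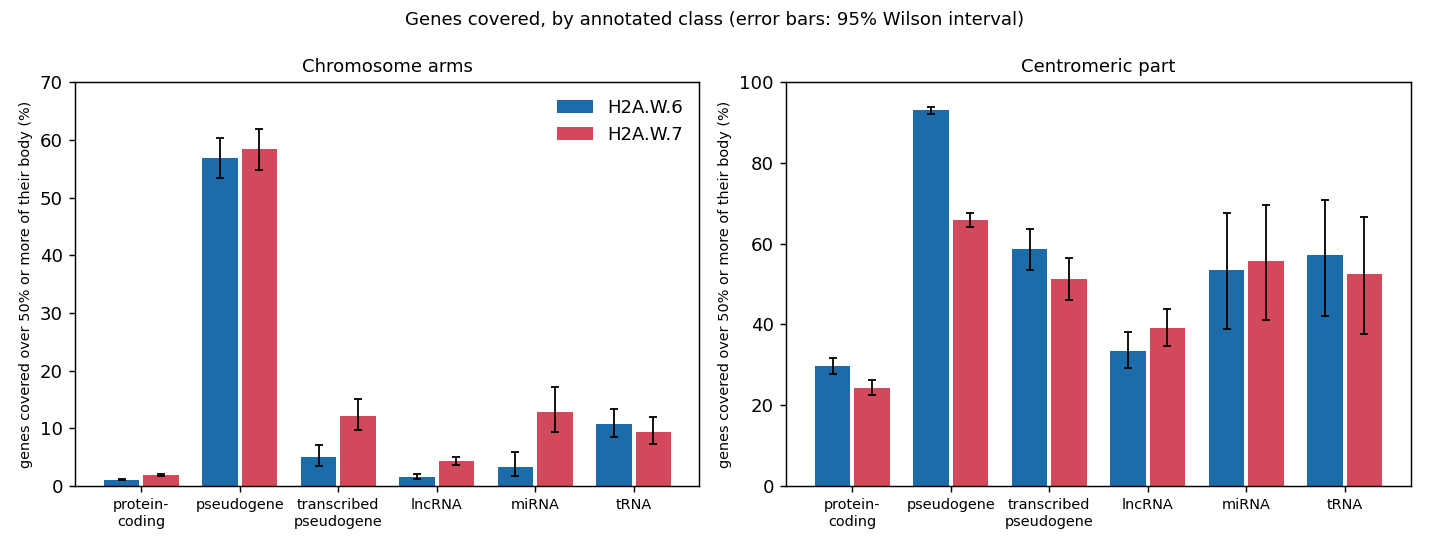
Share of genes of 6 annotated classes covered over 50% or more of their body (y axis, percent) in the arms and in the centromeric part, with H2A.W.6 in blue, H2A.W.7 in red and error bars giving the 95% Wilson interval over genes. The widest gap is that of centromeric pseudogenes, 93.0% against 65.9%.

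Among the fixed lists of genes, H2A.W.6 covered 7 of the 8 transposon loci, and no gene of the other 6 lists was covered by either variant. Of all 10 silenced loci, H2A.W.6 covered those 7 and H2A.W.7 covered 3. The retrotransposon AtGP1 was covered by both, at 100% of its body for H2A.W.6 and 99.2% for H2A.W.7, and so were ROMANIAT5 (99.1% and 64.7%) and the heat-responsive ONSEN (53.0% and 51.8%). Ta3 (99.4% and 43.3%), CACTA1 (99.5% and 16.3%), EVD (83.6% and 26.7%) and AtMu1 (79.4% and 30.3%) passed the limit for H2A.W.6 alone. SDC had 0% for H2A.W.6 and 19.7% for H2A.W.7, FWA 0% and 11.8%, and COPIA4 5.74% and 0%. Against 10000 random lists matched on biotype, compartment and length, a match chosen after seeing the data, the median was 7 covered loci for H2A.W.6 and 5 for H2A.W.7. The observed counts lay at percentiles 27.6 and 3.14, where a percentile is the share of random lists with a lower count, ties left out. The H2A.W.6 count thus equalled the random median. Against protein-coding genes, as fixed beforehand, the random median was 0 for both and the percentiles were 100 and 99.81.

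No gene was covered by either variant among the 8 H2A variant genes, 12 DNA damage response genes, 12 genes of the heterochromatin silencing machinery, 10 Polycomb targets, 10 leaf and housekeeping genes and 10 NLR resistance genes. Of these 62 genes, 0 had any H2A.W.6 base. H2A.W.7 covered 19.2% of the body of RBCS1A, which encodes a small subunit of Rubisco, and 3.91% of that of the resistance gene RPP5. Random lists of protein-coding genes had a median of 0 covered members too, so these counts do not set the lists apart from other protein-coding genes.

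The genes of 1 kb or more that differed most towards H2A.W.6 were all centromeric, and those that differed most towards H2A.W.7 were all in the arms. The first 10 were the pseudogenes AT5G32136, AT4G07795, AT3G30721, AT4G06625, AT3G30744, AT5G32112, AT2G10040, AT1G38270 and AT1G36840 and the transcribed pseudogene AT1G40089. H2A.W.6 covered 96.3% (AT1G38270) to 99.7% (AT5G32136) of their bodies, and H2A.W.7 covered 1.25% of AT2G10040, 3.12% of AT1G36840 and 0% of the other 8. The 10 in the opposite direction were the pseudogenes AT5G65676, AT3G29187, AT5G20800 and AT3G23085, the protein-coding genes AT4G02910, AT5G52115, AT5G51650, AT5G48190 and AT2G22440, and the non-coding RNA gene AT5G00650. H2A.W.7 covered 81.0% (AT3G23085) to 100% of them, and H2A.W.6 covered 13.8% of AT5G20800, 17.3% of AT5G48190, 19.5% of AT2G22440 and 0% of the other 7.

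Long pseudogenes differed in where along their body the 2 variants lay, a profile drawn after the data had been seen. In the 600 centromeric pseudogenes of 4 kb or more, H2A.W.6 covered 88.7% of the outer 500 bp at each end and 87.7% of the interior, and H2A.W.7 covered 69.1% and 57.6%. In the 184 such arm pseudogenes the values were 65.9% and 67.9% for H2A.W.6 and 70.9% and 55.1% for H2A.W.7. Protein-coding genes of 2 kb or more in the arms had little of either variant in the body, and both shares rose outside it. From the first 100 bp inside the edge to between 800 and 900 bp outside, H2A.W.6 went from 0.294% to 1.06% and H2A.W.7 from 0.857% to 4.56%. Both outer values lay below the 2.39% and 4.70% of the arms as a whole, so the rise does not show an excess beside genes.

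**Figure D3:**
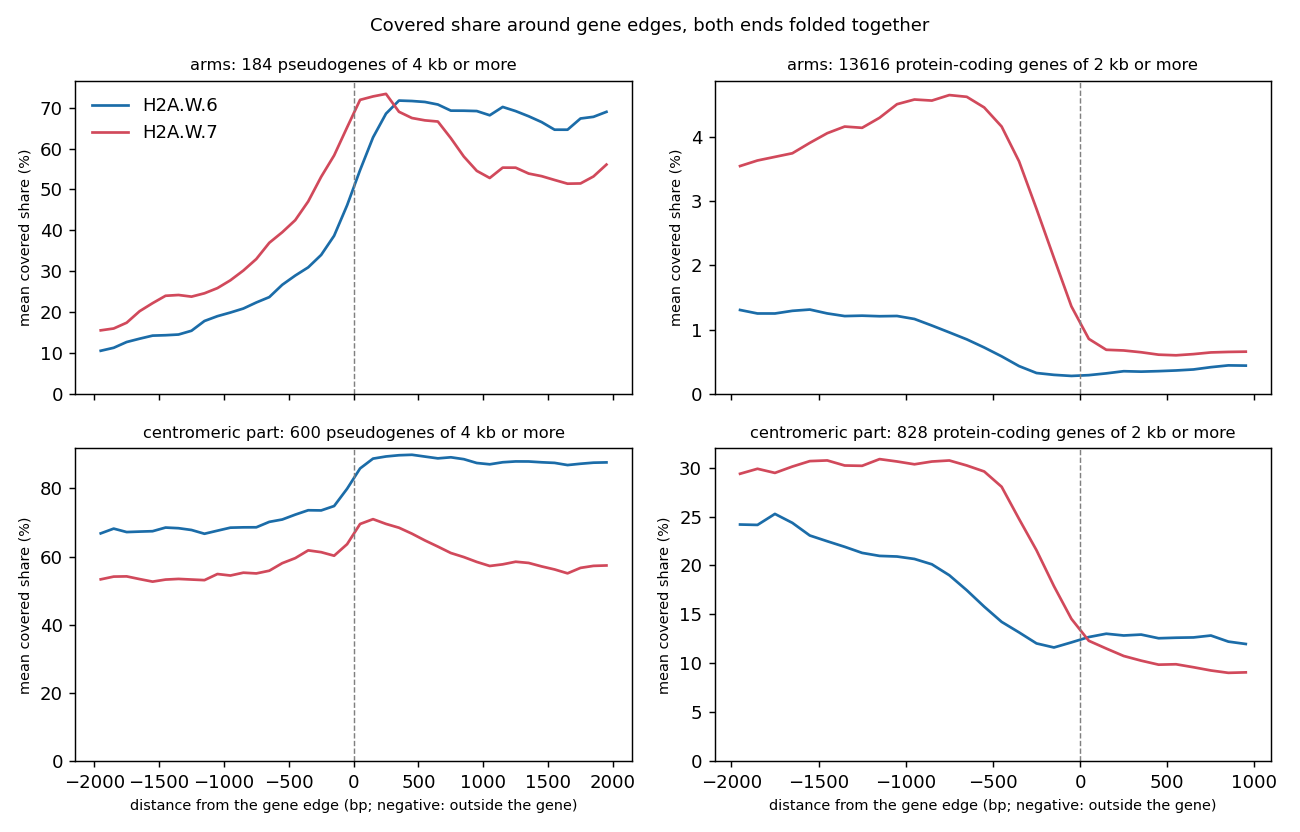
Mean share covered (y axis, percent) by distance from the gene edge (x axis, bp, negative outside the gene, both ends folded together) for long pseudogenes and protein-coding genes, with H2A.W.6 in blue and H2A.W.7 in red. Inside centromeric pseudogenes H2A.W.6 stays level while H2A.W.7 declines away from the edge, from 69.1% over the outer 500 bp to 57.6% in the interior.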

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

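The alternatives with 500 kb windows, regions of 500 bp or more, lists matched on biotype and no chromosome 2 interval were chosen after seeing the data, the others before. Of 250 alternative values for 26 results, 211 stayed within the counting interval of a share or within 1.5 times any other value and 39 moved further. The covered length ratios and the correlations across bins were among those that stayed, but outside these alternatives, the centromeric ratio was 0.476 among regions of 1000 bp or more and 0.322 for those of 2000 bp or more. The share of regions that met the other list was labelled as moved most often, in part because its counting interval is narrower than the limit of 1.5 times. The values of this share follow in the order H2A.W.6 arms, H2A.W.7 arms, H2A.W.6 centromeric, H2A.W.7 centromeric. It was 82.4%, 40.4%, 72.7% and 81.0% with regions at or above the median length, 82.7%, 32.9%, 65.2% and 86.6% when 50% of a region had to be shared, 39.4%, 20.2%, 34.9% and 28.0% with 50% in both directions, and 90.3%, 35.2%, 94.5% and 84.8% after merging within 1000 bp. With the longer list thinned, which removes regions by construction, it was 48.4% for H2A.W.6 in the arms and 72.6% for H2A.W.7 in the centromeric part. In the last 3 the centromeric share of H2A.W.6 exceeded that of H2A.W.7, opposite to the main order. Leaving out 1 chromosome at a time gave 40.3% to 42.2% for H2A.W.7 in the arms and 89.1% to 91.0% in the centromeric part. Placement inside 500 kb windows lowered the arm Jaccard ratio to 10.6 and the arm pseudogene ratios to 10.5 for H2A.W.6 and 6.10 for H2A.W.7, because it keeps the local density of regions. At 90% of the gene body, covered pseudogenes were 185 and 214 in the arms and 2260 and 859 in the centromeric part, and protein-coding genes were 83 and 225 in the arms and 399 and 277 in the centromeric part, H2A.W.6 first. With any base, protein-coding genes were 635 and 1265 in the arms and 766 and 836 in the centromeric part, where the order turned. Thinning left 182.5 arm pseudogenes and 214 arm protein-coding genes for H2A.W.7, below the 434 and 267 of H2A.W.6. In the centromeric part it left H2A.W.6 2266 pseudogenes, against 2078, and 473.5 protein-coding genes, against 510. The order thus turned in both arm counts and in centromeric protein-coding genes. It also turned for arm pseudogenes with regions at or above the median length, 376 and 374, and for the centromeric protein-coding ratio with 500 kb windows, 0.406 and 0.385. With regions of 500 bp or more, H2A.W.6 covered 147 arm protein-coding genes. Leaving out 1 chromosome gave 401 to 547 centromeric protein-coding genes for H2A.W.6 and 333 to 447 for H2A.W.7, lowest without chromosome 2. Such counts, which stand among the 250 values, fall by construction with the genes of the chromosome left out. Chromosome 2 held 648 of the 2100 centromeric protein-coding genes. Except where the construction shows it, the cause was not tested. No paired analysis was possible because each immunoprecipitation has 1 library. The alternative restricted to unique sequence was not run, and neither were exon and intron shares. Depth is unknown, so its part in the list lengths was not measured.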

Other observations

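Chosen only after the result was seen were the tests of overall sensitivity and of position outside gene bodies, and the loci of the next paragraph. The tests of short gaps, of halos and of scaling were set down before their values were known.

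Non-coding genes of the arms were covered more often by H2A.W.7. Of 283 arm miRNA genes 9 were covered by H2A.W.6 and 36 by H2A.W.7, of 3059 lncRNA genes 47 and 129, and of 563 transcribed pseudogenes 28 and 68, with H2A.W.7 higher on 5 of 5 chromosomes for each class. H2A.W.7 also covered 1.96 times as much of the arms, and the non-coding RNA classes pooled took 2.05% of the arm bases of H2A.W.6 and 2.29% of those of H2A.W.7, 0.845 and 0.937 times random placement. The classes differed, with transcribed pseudogenes at 2.12 and 1.95 times random placement and a mean cover of miRNA genes of 3.16% and 12.5%, of lncRNA genes of 1.42% and 4.10% and of tRNA genes of 10.5% and 9.14%, against 2.39% and 4.70% of the arms. Arm tRNA genes went the other way, with 62 of 583 covered by H2A.W.6 and 54 by H2A.W.7. All 62 lay in 1 array on chromosome 1, from AT1G56730 to AT1G57530, which holds 81 tRNA genes, 49 of them covered by H2A.W.7. In the outer 1000 bp of the chromosomes, H2A.W.7 covered 69% at the start of chromosome 1, 59% at that of chromosome 3, 85% at that of chromosome 5, 59.9% at the end of chromosome 2 and 86.7% at that of chromosome 5, but 1% at the start of chromosome 2 and 0% at that of chromosome 4. H2A.W.6 covered 22.5% at the start of chromosome 5 and 0% at the others named. The ends of chromosomes 2 and 5 were located only because an H2A.W.7 region ran into them, so some H2A.W.7 cover there was fixed by that choice. The ends of chromosomes 1, 3 and 4 could not be located in this way and were not measured.

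H2A.W.7 covered the edges of long centromeric pseudogenes more than their interior, 69.1% against 57.6%, while H2A.W.6 covered both alike on average, 88.7% and 87.7%, although its edge was higher in 355 of 600 pseudogenes and lower in 165, against 407 and 153 for H2A.W.7. Lower sensitivity of the H2A.W.7 list everywhere would give less cover of the arms, but its cover was larger on 5 of 5 chromosomes. That result was known when the test was chosen. It cannot decide on a lower sensitivity inside pseudogenes alone, which stays open. Short gaps that split regions stay open, since merging regions within 1000 bp left 64.1% of the H2A.W.7 difference, with 47.5% to 83.2% per chromosome, and in arm pseudogenes took it from 15.7 to 8.44 percentage points, on chromosome 5 from 12.1 to 2.03. The edge minus interior difference of H2A.W.6 fell too, from 0.983 to -1.40 points in centromeric and from -2.05 to -6.49 in arm pseudogenes. The contrast between the variants therefore fell less, from 10.5 to 8.77 points in centromeric and from 17.8 to 14.9 in arm pseudogenes. A difference between the variants in long transposons is a hypothesis that may also account for it, untested with 1 library each.

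H2A.W.7 covered more of the arms and less of the centromeric part than H2A.W.6. Halos around H2A.W.6 regions are argued against as the source of most arm bases covered by H2A.W.7 alone. Of these bases 20.7% lay within 200 bp of an H2A.W.6 region and 60.4% lay over 1000 bp away. No random placement was set beside these distances, so nearness to H2A.W.6 regions beyond chance was not measured. Halos may still give part of these bases. Scaling of each immunoprecipitation against the control cannot be told apart from a difference between the variants, because the lists hold no heights. Among regions of 1000 bp or more the ratio of H2A.W.7 to H2A.W.6 was 1.86 in the arms and 0.476 in the centromeric part, and among those of 2000 bp or more 1.42 and 0.322, against 1.96 and 0.778 among all, which describes it without deciding. A different distribution of the variants themselves remains a hypothesis.

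Arm regions found with H2A.W.7 alone often lay beside protein-coding genes, 47.5% of them outside gene bodies and within 1000 bp of such a gene, against 21.4% at random (20.2% to 22.5%). That excess came with lying outside gene bodies at all, 80.7% against 32.4%. Among the regions outside gene bodies 58.8% were that near, below the 66.1% of placements within arms (63.9% to 68.5%) and the 62.2% within 500 kb windows (60.0% to 64.6%). Position outside gene bodies alone stays open, since it leaves no excess beside genes in the arms and does not give the lower share. The bound of this test was changed after its value was seen, from outside the random range to above it. Under the earlier bound, the share below both ranges would have counted against that explanation. In the centromeric part that share was 36.8%, above the 21.8% of placements there (19.1% to 24.4%) and the 30.3% within windows (27.5% to 33.1%), and no biological explanation was tested. These regions were picked for holding no H2A.W.6 base, and placements were not. H2A.W.6 covered 58.1% of the centromeric span, with protein-coding genes at 0.308 times random placement, so that choice may give part or all of the excess.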
